A study of Mus musculus with 10 samples.

How the data were processed

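RNA was measured in 10 populations of immortalized mouse embryonic fibroblasts that carry a point mutation in mitochondrial DNA, 5 with a high and 5 with a low share of mutant genomes. The labels name the populations of each group as biological replicates, and the sample descriptions give each a different clone number. How the clones were derived is not given in the sources used here. The libraries were made by poly(A) capture with a stranded kit, pooled and read as 50 bp pairs on 1 lane as the submitters state. Their sample sheet lists 2 runs for each library, and what a run stands for is not given. The submitters' processing notes name STAR 2.7.8a, DESeq2 1.36.0 and R 4.2.1 and the mouse build GRCm38, with no role for each. The counting tool, its strand setting and the gene annotation release are not given in the sources used here.

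The deposited raw count table holds whole read counts per Ensembl gene, which the authors made with 1 column per library, so the 2 runs had been combined. The deposited normalized table holds a signal that the authors made by dividing the counts of each library by 1 size factor, and this was checked: the ratio of raw to normalized values was a single number per library and equalled the median-of-ratios size factor. The count table has 26401 genes, of which 3003 were at 0 in all libraries. Genes were named with GENCODE M21 on GRCm38. This left 195 identifiers without a name, which held at most 0.0701% of the counts of a library. Library totals ran from 17318372 to 28208576 counts.

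Changes were tested on the raw counts with edgeR 4.0.16 in R 4.3.3, with the group as the only term. Genes passed the default expression filter by group, library sizes were scaled by TMM, and robust quasi-likelihood F-tests were adjusted by Benjamini-Hochberg, with a threshold of 0.05 (two-sided). Log2 fold changes are high over low, and their SE is the fold change divided by the root of the F statistic. CPM are counts scaled to a common library size, with the TMM factor applied except for the library measures, which use raw totals. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists with at least 3 tested members, adjusted over the lists, and again with a correlation estimated per list and with fry. The 55 lists cover mitochondrial, metabolic, stress, immune and cell identity genes. The share of counts on mtDNA-encoded mRNAs was compared by a two-sided exact permutation test over all arrangements of the 10 libraries, and so were 12 further library measures and the 20 chromosomes, each adjusted within its family. A chromosome's deviation in a library is the median, over its genes with a mean log2 CPM above 3, of the difference from each gene's median over the libraries. The mitochondrial mRNAs and ribosomal RNAs were aligned with blastn 2.17.0 to the annotated transcripts of nuclear genes, to find nuclear copies.

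The genes named were set by a rule: the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM, a proper symbol and no overlap between the groups, the 13 mtDNA-encoded mRNAs, up to 4 members with the smallest p of each shifted list and of 5 further lists, all sex-linked genes, and called members of any list. Of the genes this rule selected, 2 are not reported here one by one and are counted only in the totals, and they were left out of the search for single libraries that stand apart. The lists, this rule, the tests and most alternatives were fixed before the data were examined. Comparisons by chromosome, and mt-Rnr1, mt-Ta, Krt8, Krt19, Cdh1, Gm42418, the BMP genes and the genes on in 1 group alone, lie outside this rule and were chosen after their values were seen. With 0 counts in a group, a fold is given as a bound against a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with an exact 95% interval. Intervals and floors cover counting error only.

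The alternatives were RLE and upper-quartile scaling, scaling without the mtDNA genes, no filter, a filter at 1 CPM in 5 libraries, the replicate number and the number in the sample code as blocks, each library left out, DESeq2 1.42.0, limma-voom with and without quality weights, a 2-fold minimum and a threshold of 0.1. Chosen after seeing the data were an offset per chromosome, leaving out chromosome 8 genes and leaving out the 2 libraries rich in Gm42418. Other splits of the 10 libraries were refitted for 100 draws of the 126 distinct ones. The code was tested on simulated data with known changes: it recovered 33.8% of 2-fold, 86.4% of 4-fold and 97.0% of 16-fold changes and called 0.05% of unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The sample sheet holds no measurement and was used only to match the columns to the groups.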

Results

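Polyadenylated RNA was sequenced from 10 populations of immortalized mouse embryonic fibroblasts, a cultured connective tissue cell grown from embryos. All populations carried the same C-to-T change in mitochondrial DNA, which lies in mt-Ta, the gene for the mitochondrial alanine tRNA. Cells of this kind hold mutant and normal mitochondrial genomes side by side, a state called heteroplasmy. In 5 populations the mutant share was high and in 5 it was low, and each population gave 1 library. Each population has its own clone number in the sample descriptions. The mutant share of each population is not given in the sources used here. The libraries are numbered 1 to 5 within each group. Total counts on genes were 19264064, 22111429, 26737561, 25579923 and 28208576 in high 1 to high 5. They were 17318372, 18748605, 22187910, 24967748 and 18925366 in low 1 to low 5. The high mean was 3950710 counts above the low mean, more than the SD of either group (3639200 high, 3100590 low). This difference did not pass (two-sided exact permutation p = 0.0873, adjusted p = 0.142 over a family of 13 library measures). Between 17408 and 18429 genes were detected per library.

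The comparison of high with low heteroplasmy asks how fibroblast gene expression differs with the load of the mutation. The 5 high populations had more RNA of Krt18, a keratin of simple epithelia, of the adipocyte genes Fabp4, Plin4 and Pparg, and of Atoh8, a transcription factor. They had far less RNA of Ildr2, Eif4g3, Zic5, Dkk2 and Nr2f1, of which Eif4g3 encodes a translation initiation factor and Zic5 and Nr2f1 encode transcription factors. Genes on chromosome 8 were lower as a block, whereas 0 of 126 nuclear genes for the respiratory chain passed the edgeR test (8 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom). Of 12964 genes tested, 258 rose and 372 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), together 4.86% of those tested. Of these, 150 rose and 155 fell at least 2-fold. The 5 high values lay entirely above or below the 5 low values for 537 of the 630 changed genes, and for 929 of all tested genes (7.17%, where chance gives 0.79%). The count of 630 depended on single libraries: it was 232 without high 3, 359 without high 2, 236 without low 1, 244 without low 2, 254 without low 3, 270 without low 4 and 372 without low 5. It was 56 without low 2 and low 3, the 2 libraries with more than 5000 CPM (counts scaled to a common library size) of the ribosomal RNA-like transcript Gm42418.

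**Figure D1:**
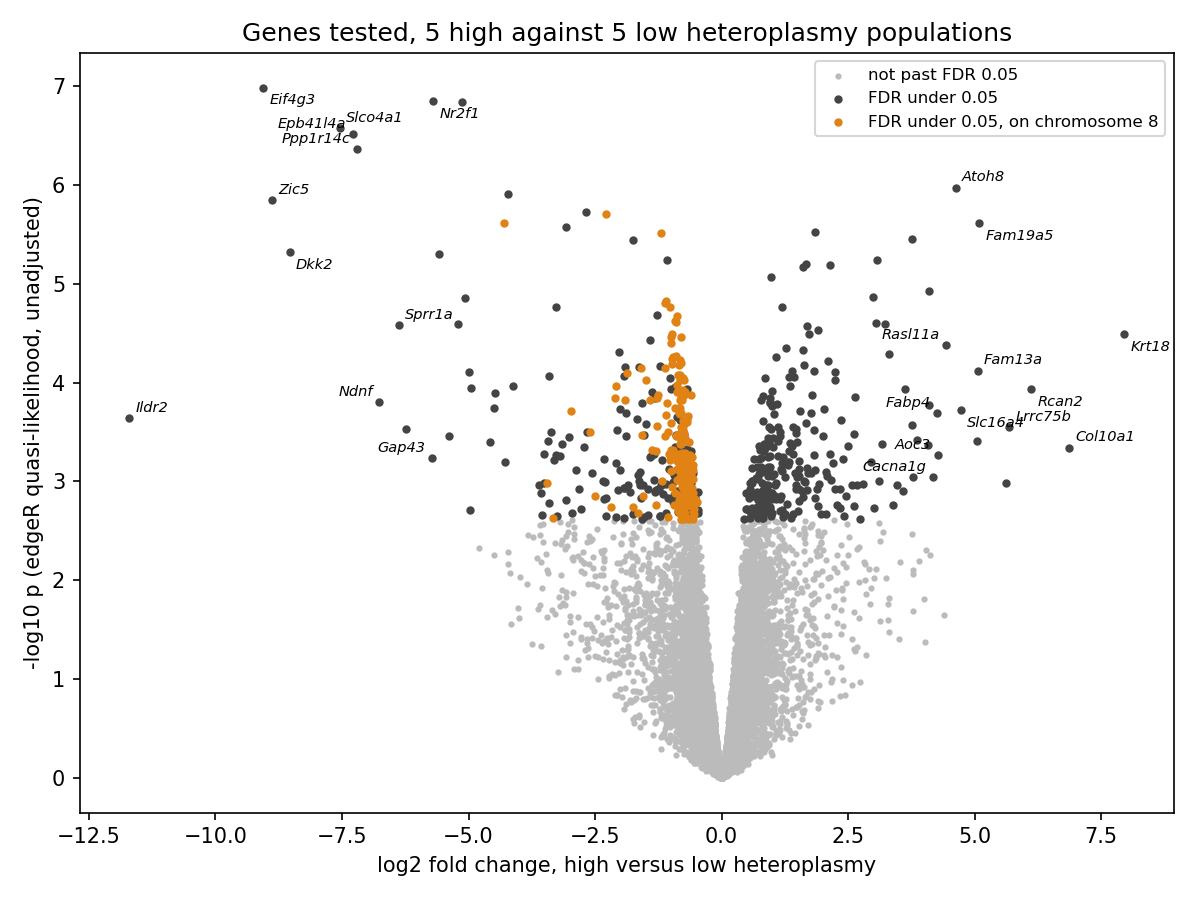
Log2 fold change, high over low heteroplasmy (x axis), against the minus log10 unadjusted p of the edgeR quasi-likelihood test (y axis) for 12964 genes, 1 point per gene, with called genes in dark grey, or in orange on chromosome 8, the others in light grey, and most of the largest changes named. The 258 rises include Krt18 at 7.95 and the 372 falls include Eif4g3 at -9.05, and the orange points all lie among the falls.

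Among the 12 largest rises, Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027 in GRCm38) went from 0.477 ± 0.12 CPM in the low to 118.8 ± 120.0 CPM in the high libraries (SD, n = 5 each), a log2 fold change of 7.95 (SE 1.18, adjusted p = 0.00895). Col10a1, a collagen of hypertrophic cartilage, rose by 6.86 (SE 1.39, adjusted p = 0.0252). It overlaps Nt5dc1 on the other strand, whose mean level was 1.64 times that of Col10a1, and its call held in 5 of the 10 fits that left out 1 library. Atoh8 rose by 4.63 (SE 0.49, adjusted p = 0.00198), from 2.93 ± 1.35 to 72.6 ± 40.9 CPM. Fabp4, a fatty acid carrier of adipocytes, rose by 4.25 (SE 0.78, adjusted p = 0.018). The other rises in this set were Rcan2, a regulator of calcineurin (6.12), Lrrc75b (5.69), Fam19a5 (5.09), Fam13a (5.06), Slc16a4 of the monocarboxylate transporter family (4.72), Rasl11a (4.44), the amine oxidase gene Aoc3 (4.27) and the calcium channel gene Cacna1g (4.17). The levels in the high group varied between populations, as for Krt18, whose SD exceeded its mean. DESeq2 called all 12, but limma-voom did not call 6 of them: Krt18 (adjusted p = 0.108), Col10a1 (0.0688), Fabp4 (0.068), Lrrc75b (0.0754), Aoc3 (0.102) and Cacna1g (0.128). With 1 library left out, the Lrrc75b call held in 9 of the 10 fits and those of Aoc3 and Cacna1g in 4.

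Among the 12 largest falls, Ildr2 had 0 counts in all high libraries against 1742 in the low libraries, which made it at least 727-fold lower against a floor of 3 counts over the high group. Zic5, a zinc finger transcription factor of neural development, also had 0 counts in the high group and was at least 113-fold lower against the same floor. Eif4g3 (ENSMUSG00000028760, chromosome 4, 137993022 to 138208508) fell from 20.04 ± 7.71 to 0.0318 ± 0.0712 CPM (SD, n = 5 each), with 4 counts left in the high group and a log2 fold change of -9.05 (SE 0.78, adjusted p = 0.000628). Dkk2, a secreted modulator of Wnt signalling, had 1 count in the high group, a low-to-high ratio of 676 (95% counting interval 121 to 26700). Ppp1r14c, a phosphatase inhibitor, also had 1 count there, a ratio of 244 (43.8 to 9640). The transporter gene Slco4a1 (log2 fold change -7.54), the cytoskeletal gene Epb41l4a (-7.29), Ndnf (-6.77), Sprr1a (-6.38), the growth-associated Gap43 (-5.73) and Nr2f1 (-5.70) were also among these falls. The Gap43 call held in 5 of the 10 fits that left out 1 library. Limma-voom called all 12 falls, and 56 of the 68 called genes that the naming rule selected. Of the 24 genes with the largest changes, 18 were called with every library left out in turn, and so were 29 of the 68.

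The changed genes were unevenly spread over the chromosomes, with chromosome 8 lower, chromosome 14 lower and chromosome 6 higher in the high group. On chromosome 8, 193 of 700 tested genes fell, among them Timm44 of the mitochondrial import motor (log2 fold change -0.88), the glutathione reductase gene Gsr (-1.10) and the mitophagy gene Fkbp8 (-0.87). In edgeR 0 chromosome 8 genes rose, where 7 were higher at an unadjusted p under 0.05, DESeq2 called 2 rises and limma-voom 0. Chromosome 8 held 5.40% of tested genes and 51.9% of the falls, and its median log2 fold change was -0.60. The median chromosome 8 deviation per library was -0.31 ± 0.14 in the high and 0.26 ± 0.10 in the low group (log2, SD, n = 5 each). That difference of -0.57 had a two-sided exact permutation p of 0.00794, the smallest that 5 against 5 libraries can give (adjusted p = 0.0397 over 20 chromosomes). Chromosome 14 had 44 falls and 2 rises with a difference of -0.40 (SD 0.13 in the high and 0.17 in the low group). Chromosome 6 had 53 rises and 3 falls with a difference of 0.30 (SD 0.18 and 0.04). Both had the same exact p, but their groups nearly met. On chromosome 6 high 4 was at -0.039 and low 4 at -0.062, and on chromosome 14 high 3 was at -0.022 and low 1 at 0.058. The differences of chromosomes 8, 14 and 6 kept their sign in all alternatives run. However, the adjusted p, which depends on how many chromosomes reach a small p, stayed under 0.05 with upper-quartile scaling alone (0.0317). It was 0.0529 with RLE scaling and with scaling without mtDNA genes. With any 1 library left out the adjusted p of chromosomes 8 and 14 was above 0.05: without high 3 or high 4 (0.0529), high 1, low 1, low 2 or low 3 (0.0794), high 2 (0.0952), and high 5, low 4 or low 5 (0.106). Chromosome 6 had the same values but for high 1 (0.136) and low 1 (0.106). Chromosome 15 reached an exact p of 0.00794 with a difference of 0.07 only, and chromosome 10, with 36 rises and 3 falls, differed by 0.28 (exact adjusted p = 0.113). Outside chromosome 8, 179 genes fell and 258 rose. When each library's median shift per chromosome was taken out, 164 genes were called, and 22 of the 24 genes with the largest changes were among them.

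**Figure D2:**
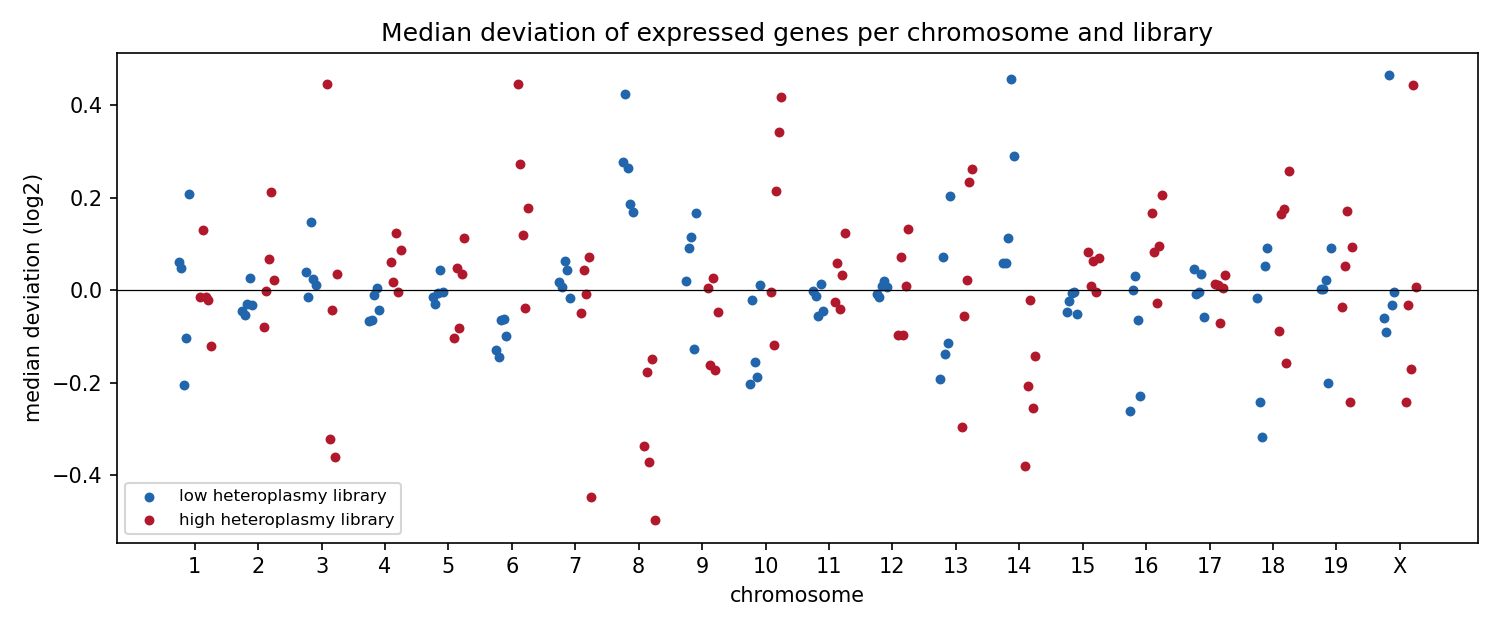
Median log2 deviation of the expressed genes of each chromosome (y axis) in each of the 5 high (red) and 5 low (blue) libraries, 1 point per library, by chromosome (x axis). On chromosome 8 the high libraries average -0.31 and the low libraries 0.26, with no overlap.

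In edgeR, transcripts of mitochondrial DNA itself changed in 1 ribosomal RNA, not in the tested mRNAs. The large ribosomal RNA mt-Rnr2 (ENSMUSG00000064339, mitochondrial genome, 1094 to 2675) rose from 2898 ± 796 to 5766 ± 1111 CPM (SD, n = 5 each), a log2 fold change of 0.99 (SE 0.22, adjusted p = 0.0326). The small ribosomal RNA mt-Rnr1 was at -0.95 and did not pass in edgeR (adjusted p = 0.0901). Its share of counts was 0.0443% in the high and 0.082% in the low libraries (exact permutation p = 0.0476, adjusted p = 0.0884). The list of mitochondrial ribosomal and transfer RNAs did not shift (camera adjusted p = 0.957), with 1 up and 1 down adjusted over the list alone. DESeq2 also called 1 rise and 1 fall in this list, and limma-voom 1 rise and 0 falls. The call of mt-Rnr2 held in 4 of the 10 fits that left out 1 library and was lost without high 2 (adjusted p = 0.0607), high 3 (0.0724), low 1 (0.0698), low 2 (0.0722), low 3 (0.0538) or low 4 (0.0616). It was also lost, at about the same fold, with the replicate number as a block (log2 fold change 1.02, adjusted p = 0.0737), the code number as a block (0.97, 0.0757) and the offset per chromosome (0.99, 0.0541). Poly(A) capture recovers ribosomal RNA only in part, and the ribosomal RNA-like Gm42418 was lower in every high (783 to 1134 CPM) than in every low library (1164 to 40196 CPM, exact permutation p = 0.00794, adjusted p = 0.0258 over 13 measures). The log2 ratio of mt-Rnr2 to mt-Rnr1 was 3.78 ± 0.66 in the high and 1.82 ± 0.49 in the low libraries (exact permutation p = 0.00794, adjusted p = 0.0258 over 13 measures). The mtDNA-encoded mRNAs, which encode subunits of the respiratory chain, took 2.48% ± 1.4 of counts in the high and 1.74% ± 0.65 in the low libraries (SD, n = 5 each). This difference of 0.74 percentage points was within the spread of the libraries (two-sided exact permutation p = 0.333), and was 0.19 without high 1.

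Of the 13 mtDNA-encoded mRNAs, 7 were tested and 0 passed in edgeR, DESeq2 and limma-voom, with 0 at an unadjusted p under 0.05 and a camera adjusted p of 0.454 for the list. Their log2 fold changes were 0.81 for mt-Cytb (SE 0.46), 0.72 for mt-Nd4, 0.62 for mt-Nd5, 0.55 for mt-Nd2, 0.38 for mt-Nd1, 0.20 for mt-Co1 and 0.06 for mt-Nd6. The sign of the last 2 turned without high 1, to -0.09 for mt-Co1 and -0.43 for mt-Nd6, and for mt-Nd6 also without low 3 (-0.13). mt-Nd6 (13552 to 14070) is on the other strand and overlaps only the end of mt-Nd5 (11742 to 13565), which had 27.7 times its level. The other 6 (mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l) had 0 to 2 counts per library, too few to compare. Annotated transcripts of nuclear copies on chromosome 1 match 21.1% of the length of mt-Atp8 and at least 99% of the length of the other 5. Their identity is at least 99.7%. Sequence outside annotated transcripts was not searched, so the value for mt-Atp8 may miss part of a copy. The mRNA share thus rests on the 7 tested mRNAs. mt-Ta, the gene that holds the mutation, had 0 to 4 counts per library, so its level was not measurable here.

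**Figure D3:**
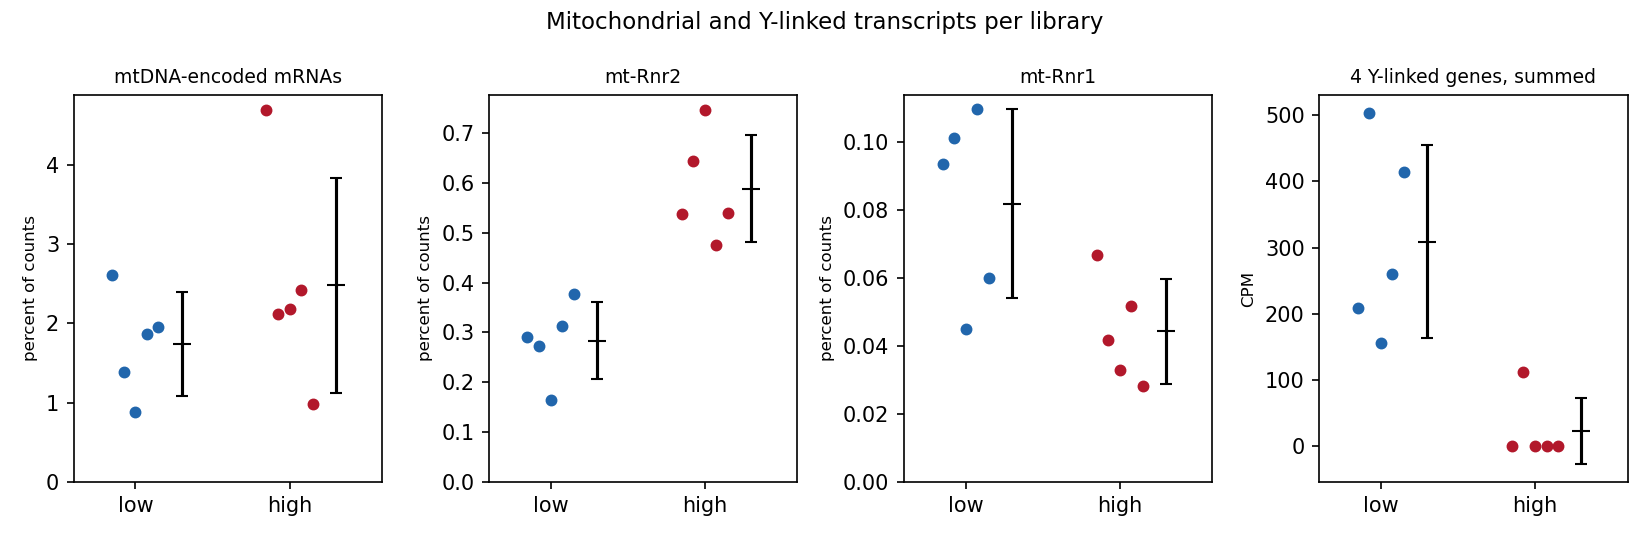
Percent of counts on mtDNA-encoded mRNAs, on mt-Rnr2 and on mt-Rnr1, and summed CPM of 4 Y-linked genes (y axes) in the 5 low (blue) and 5 high (red) libraries, 1 point per library, with the group mean and SD in black. The mt-Rnr2 share averages 0.589% in the high and 0.283% in the low libraries with no overlap, and the Y-linked sum does not overlap either, while the mRNA share does.

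Nuclear genes for mitochondrial proteins showed few changes. The 126 tested subunits and assembly factors of the respiratory chain and ATP synthase, of which none passed in edgeR, had camera adjusted p values of 0.442 to 0.957 by list. Complex I subunits had a median log2 fold change of 0.06, with Ndufa9 at 0.44 and Ndufb7, on chromosome 8, at -0.54, neither past the threshold. The medians were 0.00 for complexes II and III, -0.01 for complex IV, 0.02 for complex V and 0.14 for assembly factors. Of 231 tested genes for mitochondrial gene expression, import and quality control, 5 fell: Timm44, the mitochondrial cysteinyl-tRNA synthetase gene Cars2 (-1.12, SE 0.16, adjusted p = 0.00661), the mitochondrial ribosomal protein gene Mrps31 (-0.76), the tRNA-modifying Gtpbp3 (-0.70) and the membrane insertase gene Oxa1l (-0.68). All but Oxa1l, which is on chromosome 14, lie on chromosome 8, and none of the 5 was called after the chromosome shift was taken out, which left Cars2 at -0.56 (SE 0.13, adjusted p = 0.0618), Timm44 at -0.32, Oxa1l at -0.26, Mrps31 at -0.21 and Gtpbp3 at -0.12. With 1 library left out, the Timm44 and Cars2 calls held in all 10 fits, Mrps31 in 7, Oxa1l in 4 and Gtpbp3 in 2. Adjusted over the list alone, 3 tRNA synthetase genes, 3 translation factors and 1 gene each of complex IV, ribosomal proteins and import fell, and 0 RNA processing genes. Cars2 overlaps Naxd on the other strand, which had 1.97 times its level.

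In those 7 lists camera gave no shift: adjusted p was 0.852 for mitochondrial ribosomal proteins, 0.704 for mitochondrial aminoacyl-tRNA synthetases, 0.483 for mtDNA maintenance and transcription, 0.483 for mitochondrial RNA processing, 0.704 for mitochondrial translation factors, 0.957 for import and 0.742 for chaperones and proteases. The members with the smallest p went both ways and did not pass. For mtDNA maintenance and transcription they were Tk2 (-0.57), Polrmt, the mitochondrial RNA polymerase (0.51), Lig3 (0.57) and Mterf2 (0.47). For chaperones and proteases they were the protease Spg7 (-0.53), Htra2 (0.47), Trap1 (0.54) and Stoml2 (-0.34). Mitochondrial dynamics and mitophagy had 2 rises, Mtfr1l (0.74) and Mief2 (0.50), and 2 falls, Fkbp8 (-0.87) and the mitophagy receptor Bnip3l (-0.71), with no shift of the list (adjusted p = 0.209; 3 rose and 2 fell adjusted over the list alone). The Fkbp8 call held in all, the Mtfr1l call in 4, the Mief2 call in 0 and the Bnip3l call in 1 of the 10 fits that left out 1 library. None of these was called after the chromosome shift was taken out. Fkbp8 on chromosome 8 was then at -0.30 (adjusted p = 0.213) and Bnip3l on chromosome 14 at -0.31 (0.45). Mtfr1l was at 0.64 (0.0532) and Mief2 at 0.45 (0.0731). Nfs1, the cysteine desulphurase of iron-sulphur cluster synthesis, was the 1 of 28 genes for coenzyme Q and iron-sulphur clusters that rose (0.45, adjusted p = 0.0496), with 0 adjusted over the list alone or by limma-voom, and the call held in 1 of the 10 fits that left out 1 library. TCA cycle (median 0.04, adjusted p = 0.695), fatty acid oxidation (0.25, 0.187) and mitochondrial antioxidant genes (0.11, 0.442) had no called member, although 1 antioxidant gene was higher adjusted over the list alone. Of the mitochondrial biogenesis regulators 1 of 15 rose, Pparg (2 adjusted over the list alone; list adjusted p = 0.483).

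By camera 9 of the 52 lists with enough tested members shifted, 1 up and 8 down, 0 of them with an estimated correlation and 5 without low 3. With fry 3 lists passed, 2 of the 9 (adipocyte markers and sex-linked genes) and the neural and glial markers. That is its test for a shift in 1 direction, the one meant by fry elsewhere. Its test for changes in either direction passed 27 lists, among them mitochondrial dynamics and mitophagy (adjusted p = 7.21e-05) and mitochondrial import (0.00152). Other groupings of the libraries reached 9 shifted lists by camera as well: 73 of 100 drawn splits, the real one included, gave at least 9 lists. The ATF4 integrated stress response, the programme of amino acid and chaperone genes that cells switch on under mitochondrial stress, was lower in the high group, with a median log2 fold change of -0.46 (camera adjusted p = 0.0166, adjusted p = 0.836 with an estimated correlation). Of its 39 tested members 1 fell, both over all genes and adjusted over the list alone: Eif4ebp1, a repressor of cap-dependent translation (-1.18, SE 0.27, adjusted p = 0.0338). Its call held in 3 of the 10 fits that left out 1 library and was lost when the chromosome shift was taken out (-0.64, SE 0.24, adjusted p = 0.206). Atf4 itself (-0.59), Slc7a5 (-0.97) and Cebpg (-0.51) did not pass. The hypoxia response was lower too (median -0.57, adjusted p = 0.0137, adjusted p = 0.836 with an estimated correlation), and 2 of 22 genes fell, or 6 adjusted over the list alone. They were Egln1, an oxygen sensor (-1.30), and Ankrd37 (-2.61), which overlaps the 5.95 times more abundant Ufsp2 on the other strand. The Egln1 call held in 5 and the Ankrd37 call in 9 of the fits that left out 1 library. Eif4ebp1, Egln1 and Ankrd37 lie on chromosome 8. After the chromosome shift was taken out Egln1 was at -0.73 (SE 0.26, before 0.27, adjusted p = 0.179) and Ankrd37 at -2.02 (SE 0.52 before and after, adjusted p = 0.0846), neither called, although most of the Ankrd37 fall remained. The stress response shift was lost without high 1 (adjusted p = 0.104), low 3 (0.252) or low 4 (0.0677), with the code number as a block (0.0538) and without the 2 libraries rich in Gm42418 (0.0947). The hypoxia shift was lost without high 4 (0.126), low 1 (0.0939) or low 3 (0.118) and held without the Gm42418-rich libraries (0.0228), and both were lost with fry (0.385 and 0.314). Over all alternatives adjusted p ran from 0.000155 to 0.836 and from 0.000466 to 0.836.

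Other stress lists held few changes. In the NRF2 antioxidant list the glutathione transferase genes Gstm2 (2.25, SE 0.37, adjusted p = 0.0135) and Gstm1 (1.32) rose while Gsr on chromosome 8 fell (3 and 2 adjusted over the list alone; list adjusted p = 0.704). Herpud1, of endoplasmic reticulum protein degradation, fell (-1.59) as 1 of 22 genes of the unfolded protein response (adjusted p = 0.209), and Farsa fell (-0.77) as 1 of 19 cytosolic aminoacyl-tRNA synthetase genes (0.067), or 4 adjusted over the list alone. Both lie on chromosome 8. Cytosolic heat shock genes (adjusted p = 0.983) and p53 targets (0.742) had no called member, with 1 p53 target up and 1 down adjusted over the list alone. Npc1, a lysosomal cholesterol carrier (0.74), and Gpnmb (3.58) rose as 2 of 35 lysosome and autophagy genes (0.93), where 4 were higher and 3 lower adjusted over the list alone. With 1 library left out, the calls of Gstm2, Gsr, Herpud1 and Farsa held in all 10 fits, Gstm1 in 5, Gpnmb in 3 and Npc1 in 2. After the chromosome shift was taken out Gsr was at -0.54 (adjusted p = 0.0847), Herpud1 at -1.03 (0.0646) and Farsa at -0.21 (0.464), none called. Gpnmb (0.0837) and Npc1 (0.079) were not called either, while Gstm2 (0.00642) and Gstm1 (0.026) stayed called.

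In metabolism, cholesterol synthesis was lower in the high group (median log2 fold change -0.22, camera adjusted p = 0.033, adjusted p = 0.836 with an estimated correlation). Of 24 genes 2 fell, or 5 adjusted over the list alone: Msmo1 on chromosome 8 (-1.27, SE 0.23, adjusted p = 0.0159) and Cyp51 (-0.84, SE 0.19, adjusted p = 0.0328). Fdft1 (-0.74) and Mvd (-0.77) did not pass. The shift was lost without high 1 (adjusted p = 0.318), low 2 (0.102), low 3 (0.0791) or low 5 (0.234). It was also lost with the replicate number as a block (0.0546), without chromosome 8 genes (0.0526), without the 2 libraries rich in Gm42418 (0.209) and with fry (0.361), with a range over all alternatives of 0.00369 to 0.836. Of the glycolysis genes Gpi1 fell (-0.69) as 1 of 28 (0 adjusted over the list alone). Ldha at -0.79, Ldhb at -3.63 and Aldoc at 2.84 did not pass (list adjusted p = 0.442). Asl, of the urea cycle, fell (-0.52) as 1 of 20 proline and glutamine genes (0.483), and Cda, cytidine deaminase, rose (0.90) as 1 of 29 nucleotide synthesis genes (0.704). With 1 library left out, the Msmo1 call held in all 10 fits, Cyp51 in 4 and Gpi1, Asl and Cda in 1 each. After the chromosome shift was taken out Msmo1 was at -0.73 and not called (adjusted p = 0.113), while Cyp51 stayed called (-0.85, 0.0491). Gpi1 (0.12), Asl (0.0563) and Cda (0.0975) were not called. Serine and one-carbon metabolism (0.936) and fatty acid synthesis (0.187) had no called member.

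Interferon-stimulated genes, the antiviral programme, were lower in the high group: all 42 tested members had negative log2 fold changes, with a median of -1.88 (camera adjusted p = 6.51e-08, adjusted p = 0.836 with an estimated correlation). Of the 42, 3 fell over all genes in edgeR and 9 adjusted over the list alone, while DESeq2 called 14 and limma-voom 0. They were Rsad2, an antiviral enzyme (-4.97, SE 1.23, adjusted p = 0.045), the chemokine gene Cxcl10 (-3.56) and Ifit2 (-1.54). Their calls held in 2, 1 and 2 of the 10 fits that left out 1 library. The mean deviation of the list was 1.42, 2.14 and 2.60 in low 2, low 3 and low 4, while low 1 was at -0.17 and low 5 at -1.58, and the high libraries ran from -2.79 to 0.29. Low 2 and low 3 were also the libraries with the most Gm42418, at 40196 and 7703 CPM. Without them camera still called the list lower (adjusted p = 0.00103). Of the remaining low libraries, however, only low 4 lay above the range of the high libraries, so this result rests on 1 library. Antigen presentation genes were lower too (median -1.61, camera adjusted p = 3.51e-05, adjusted p = 0.836 with an estimated correlation). Camera also called that shift without low 2 and low 3 (0.00433). The remaining low 1, low 4 and low 5 were then at 0.133, 1.985 and -1.024, against -1.347 to -0.029 in the high libraries, so low 4 weighed most. Of 18 genes 2 fell in edgeR, or 12 adjusted over the list alone: the class I gene H2-D1 (-1.57) and the immunoproteasome gene Psmb10 on chromosome 8 (-2.19). Both calls held in 2 of the 10 fits that left out 1 library, and limma-voom called neither (adjusted p = 0.0606 and 0.0567). After the chromosome shift was taken out H2-D1 was at -1.56 (adjusted p = 0.0818) and Psmb10 at -1.67 (0.132), neither called. Nlrc5, the class I transactivator, was at -2.93 and H2-K1 at -1.74, neither past the threshold. NF-kB inflammatory genes had a median of -0.59 (adjusted p = 0.0441, adjusted p = 0.836 with an estimated correlation) with 1 of 18 fallen, the cytokine gene Lif (-1.82), also 1 adjusted over the list alone, whose call held in 2 of the 10 fits. Ccl2 was at -1.79 and Cxcl12 at 4.12 without passing. The NF-kB shift was lost without high 2 (adjusted p = 0.0899), high 3 (0.073), high 4 (0.126), high 5 (0.105), low 1 (0.102), low 3 (0.121) or low 4 (0.0677), with the code number as a block (0.0872) and without the 2 libraries rich in Gm42418 (0.123). With fry the interferon (0.314), antigen presentation (0.288) and NF-kB lists (0.288) did not pass. Over all alternatives the adjusted p ran from 1.12e-16 to 0.836 for the interferon list, from 1.53e-10 to 0.836 for antigen presentation and from 0.00465 to 0.836 for NF-kB.

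**Figure D4:**
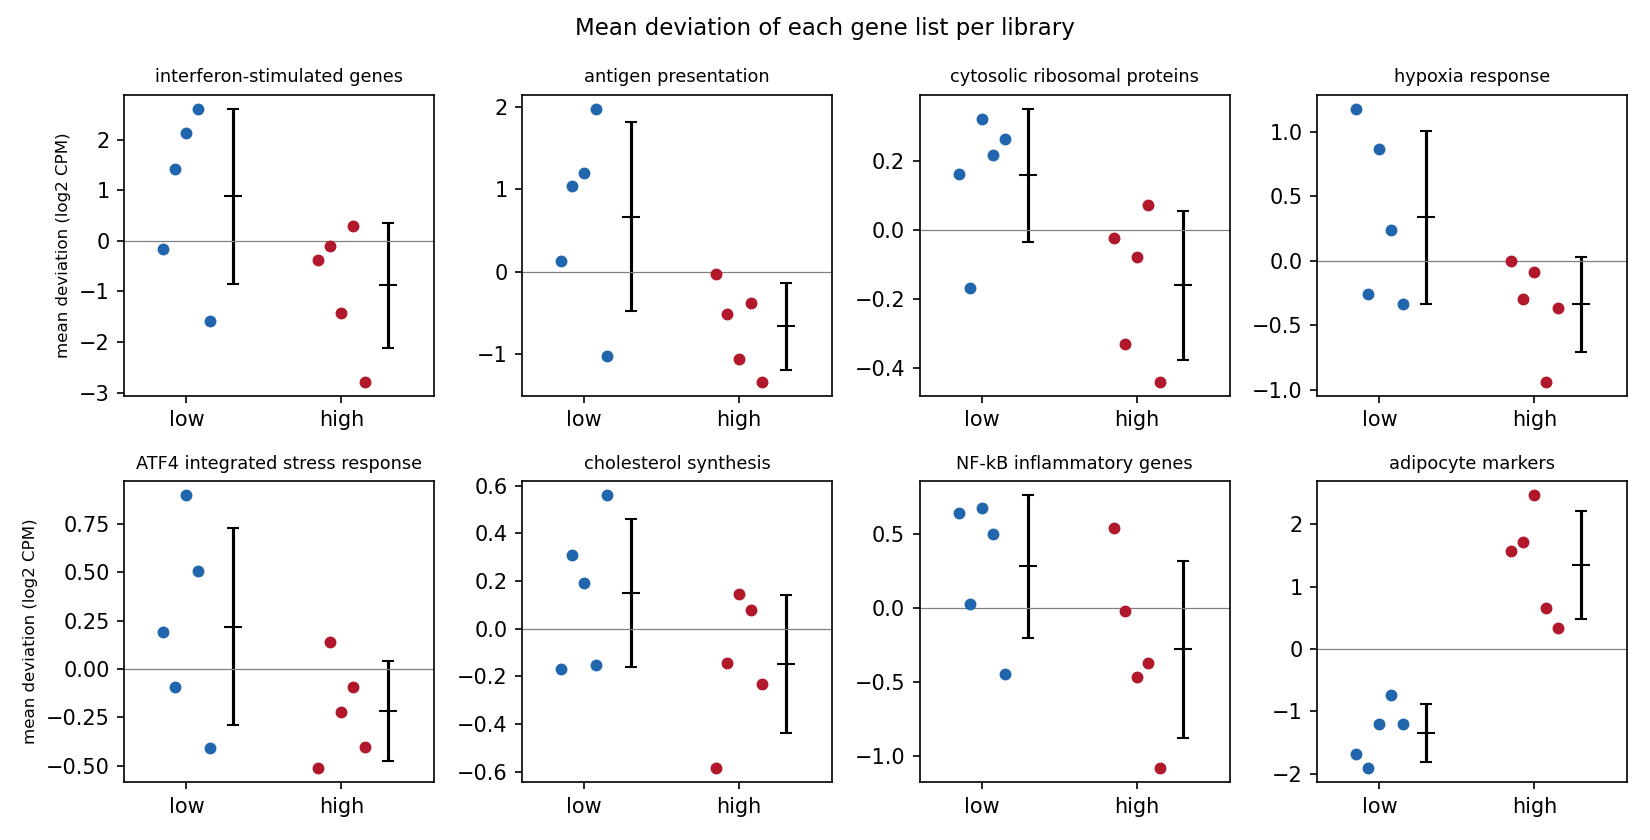
Mean log2 CPM deviation of the tested genes of 8 lists from their mean over the 10 libraries (y axes) in the 5 low (blue) and 5 high (red) libraries, 1 point per library, with the group mean and SD in black. The groups overlap in all lists shown but the adipocyte markers, where the high libraries lie between 0.34 and 2.47 and the low between -1.91 and -0.74.

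Cytosolic ribosomal protein genes were lower by a small, even amount: 72 of 76 were negative, with a median of -0.32 (camera adjusted p = 1.1e-07, adjusted p = 0.836 with an estimated correlation). Of the 76, 4 fell, or 6 adjusted over the list alone, among them Rpl15 (-0.77) and Rps24 (-0.67) on chromosome 14 and Rpl29 (-0.58). The calls of these genes held in 3, 2 and 1 of the 10 fits that left out 1 library. After the chromosome shift was taken out Rpl15 was at -0.35 (adjusted p = 0.205), Rps24 at -0.26 (0.362) and Rpl29 at -0.455 (0.106), none called. The ribosomal protein genes together took 4.43% ± 0.42 of counts in the high and 5.27% ± 0.59 in the low libraries (exact permutation p = 0.0397, adjusted p = 0.0884). MYC targets and ribosome biogenesis (median 0.01, adjusted p = 0.822), G1/S (0.01, 0.541) and G2/M cell cycle genes (0.01, 0.742) and inhibitors and senescence genes (-0.09, 0.463) had no called member, with 2 G1/S genes lower adjusted over the list alone. Across alternatives the adjusted p of the ribosomal protein list ran from 7.39e-12 to 0.836, and it was 0.288 with fry.

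Markers of cell identity moved in a few genes each. Of the 12 adipocyte markers 11 were in the count table and 3 passed the expression filter, so the list test rests on these 3. The filter works by group, so a gene expressed in 1 group alone can pass it. All 3 rose, adjusted over the list alone as well: Fabp4, the lipid droplet gene Plin4 (3.07, SE 0.39, adjusted p = 0.00344) and Pparg, the regulator of adipocyte formation (1.45, SE 0.32, adjusted p = 0.0315). The list shifted up (camera adjusted p = 0.000399, range over alternatives 0.000205 to 0.833, with adjusted p = 0.833 with an estimated correlation). Plin4 overlaps the 4.56 times more abundant Hdgfl2 on the other strand, and the Pparg call held in 2 of the 10 fits that left out 1 library. With the chromosome shift taken out Pparg, on chromosome 6, was at 1.16 and not called (adjusted p = 0.102). In the epithelial list Krt18 rose while its partner Krt8 (-1.4), Krt19 (-1.39) and Cdh1 (-2.73) did not pass in edgeR (list adjusted p = 0.172). Of the 6 tested, 4 were lower adjusted over the list alone and by DESeq2 and 1 by limma-voom, which did not call the Krt18 rise. Of 5 cartilage and bone markers 1 rose in edgeR, Col10a1 (0.483), and 0 by limma-voom. Of 5 neural and glial markers 2 fell, the filament gene Nes (-1.32, SE 0.24, adjusted p = 0.0159) and Tubb3 on chromosome 8 (-1.55), with a list adjusted p of 0.121 by camera and 0.0131 by fry. In the myofibroblast list Tpm1 (-0.87) and Ccn1 (-1.30) fell (0.525), in the matrix remodelling list Plau fell (-0.96; 0.641) and of 25 Hox genes Hoxb9 fell (-2.29; 0.483). Adjusted over the list alone, 3 were higher and 3 lower in the myofibroblast list, 2 and 3 in the matrix list, and 2 Hox genes were lower. With 1 library left out, the Nes call held in all 10 fits, Plau in 3, Tubb3 and Ccn1 in 2 and Tpm1 and Hoxb9 in 1. After the chromosome shift was taken out Nes stayed called (-1.25, adjusted p = 0.0276). Tubb3 was at -1.02 (0.139) and Plau, on chromosome 14, at -0.62 (0.216), neither called. Tpm1 (0.0847), Ccn1 (0.057) and Hoxb9 (0.0831) were not called either. Fibroblast identity genes (0.704; 2 higher and 2 lower adjusted over the list alone) and imprinted genes (0.704; 1 lower) had no called member. Skeletal muscle, endothelial and macrophage markers had 2, 1 and 2 tested members, too few for camera, and 0 were called. The lists without a called gene held 460 tested genes, of which 60 had an unadjusted p under 0.05, 21 were called by DESeq2 and 11 by limma-voom.

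Y-linked transcripts were lower in each high library than in any low library, and near 0 in 4 of the 5. The summed level of Kdm5d, Ddx3y, Uty and Eif2s3y was 0 CPM in high 1, high 3 and high 4, 0.0709 CPM in high 5 and 112 CPM in high 2. It was 155 to 504 CPM in the 5 low libraries, and the difference in means had a two-sided exact permutation p of 0.00794 (adjusted p = 0.0258 over 13 measures). None of the 4 genes passed in edgeR (adjusted p 0.155 for Uty, 0.169 for Eif2s3y, 0.215 for Ddx3y and 0.22 for Kdm5d), while 4 had an unadjusted p under 0.05 and 4 were called adjusted over the list alone and by limma-voom, and 0 by DESeq2. The list was lower by camera (median -3.87, adjusted p = 4.73e-05, adjusted p = 0.836 with an estimated correlation, range over alternatives 1.64e-15 to 0.836). Xist, the X inactivation transcript, was at most 0.136 CPM in any library.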

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

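Of the tests below, the search for a library swap, the Xist level and the ratio of the 2 mitochondrial ribosomal RNAs were chosen only after the result was seen. In 380 checks, each of 1 measure in 1 group of 5 libraries, 21 found a library whose gap to the nearest of the others exceeded 0.71 of the group's range. Chance gives about 19, so a flag by itself carries little weight. The checks are not independent, and the Y-linked signal of high 2 is among the 21 several times, so this comparison does not judge the size of a single case.

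Several of these concerned whole libraries. Low 2 had 40196 CPM of Gm42418, against 1164 to 7703 in the other low libraries. Its 10 most abundant genes took 7.92% of counts, against 4.69 to 5.13% in the others of its group. High 2 had 112.3 CPM on Y-linked genes, against 0 to 0.0709 in the other high libraries, and a mean log2 deviation of 2.52 for the sex-linked list, against -5.59 to -5.39. The median log2 deviation was -0.45 for chromosome 7 in high 5 (others -0.05 to 0.07), -0.071 for chromosome 17 in high 3 (others 0.01 to 0.03) and 0.47 for the X chromosome in low 3 (others -0.09 to 0.00). The mean log2 deviation was -0.19 for mitochondrial ribosomal proteins in low 2 (others 0.00 to 0.08), -0.075 for coenzyme Q and iron-sulphur cluster genes in high 2 (others 0.05 to 0.09) and 0.89 for Hox genes in high 1 (others -0.67 to -0.33).

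Single genes also had 1 library apart from the other 4 of its group, in log2 CPM. Fdft1 was at 7.88 in low 5, above the others at 7.02 to 7.25. Mrps31 was at 5.58 in low 2, below 5.75 to 5.81. Tpm1 was at 8.87 in high 3, below 9.13 to 9.17, and Eif4ebp1 was at 7.66 in high 4, above 6.46 to 6.73. In high 2 the Y-linked Kdm5d was at 4.51, Ddx3y at 5.19, Uty at 3.64 and Eif2s3y at 5.15, where the other high libraries were at the value of 0 counts, -3.49, but for Eif2s3y in high 5. Ppp1r14c and Dkk2 at -2.92 in high 2, and Eif4g3 at -2.01 in high 4, were the only high libraries with counts of these genes.

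The lower level of chromosome 8 genes in the high group was weighed against library scaling, sequence composition, depth and chromosome copy number. Scaling cannot separate chromosomes, yet chromosome 8 lay -0.64 below the other autosomes (median log2 fold change, spread 0.173), and removing the trend on GC content and transcript length left -0.67 (spread 0.316). Thinning all libraries to the smallest total left -0.60, but thinning acts on all genes of a library alike and could hardly have moved this median. It therefore says little on depth, while the values before it argue against scaling and sequence composition. The lower level ran along the whole chromosome, with a highest median of -0.51 among 4 equal parts of its genes in order. That is consistent with fewer copies of chromosome 8 in the high populations or more in the low ones, a hypothesis that RNA alone cannot settle, and whether it follows from the mutation or from the descent of the clones stays open.

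The Y-linked transcripts near 0 in 4 of 5 high libraries were weighed against exchanged libraries and female cells. A swap of high 2 with a low library would leave a low library without them, but the lowest low library had 155.1 CPM. A wrong label on high 2 is argued against by 82.8% of 338 of the 359 genes called without it (5 on the Y chromosome and 16 not tested with all libraries left aside), which placed it nearer to the high mean (95% interval 78.4 to 86.7%, though genes are not independent). The 4 libraries had at most 0.0748 CPM of Xist, which does not tell female cells with a single X chromosome from male cells that lost the Y chromosome. The median X chromosome deviation of high 4, which had no Y-linked counts, was 0.44 (log2). It was 0.47 in low 3, which had them, so the X level does not decide either. Other states of the X chromosome were not tested. The cause may have arisen as the populations were derived, and a link to heteroplasmy was not tested.

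The higher mt-Rnr2 in the high group was weighed against a general rise of mitochondrial RNA and against ribosomal RNA carried through poly(A) capture. The log2 ratio of mt-Rnr2 to the mtDNA-encoded mRNAs differed by 0.66, within the spread of 1.20 (exact permutation p = 0.127). This met the bound set beforehand for a general rise, and by itself excludes nothing. The ratio to mt-Rnr1 differed by 1.97 (spread 1.15, exact permutation p = 0.00794, the smallest possible). That ratio restates the opposite directions of the 2 ribosomal RNAs, which had been seen before: in the captured RNA they did not rise together. Whether the cells held more of all mitochondrial RNA or of both ribosomal RNAs is not decided, since capture may have changed the ratio. The difference in the ratio to mt-Rnr1 was 1.86 without the 2 libraries rich in Gm42418 (exact permutation p = 0.0179). The other 3 low libraries still had more Gm42418 than any high library (1164 to 1569 against 783 to 1134 CPM). The test thus did not balance carry-over, and the bound set for it beforehand does not decide. A difference in carry-over, in the short A tails of the ribosomal RNAs or in their amounts stays open, as does a link to heteroplasmy.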

How the results depend on the processing

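The offset per chromosome, the fit without chromosome 8 genes and the fit without the 2 libraries rich in Gm42418 were chosen only after the result was seen. The 630 changed genes became 1475 with DESeq2 (all 630 among them), 1276 at a threshold of 0.1 and 305 with a 2-fold minimum, a looser or stricter rule by construction for the last 2. They became 164 with the offset per chromosome, 280 without chromosome 8 genes and 56 without the libraries rich in Gm42418, where fewer libraries or genes were tested in the last 2. With 1 library left out they ran from 232 to 821. With the replicate number as a block they were 577, of which 415 were shared, and the numbers did not pair the libraries: same-numbered correlations ran from -0.05 to 0.46, and 2 of 5 high libraries correlated best with their own number. With the code number as a block they were 479, of which 310 were shared. RLE, upper-quartile and mtDNA-free scaling, the filters and limma-voom stayed within 1.5 times of 630. Shifted lists, 9, became 0 with an estimated correlation, 3 with fry (2 of them among the 9) and 5 to 11 with 1 library left out, and were 8 with the replicate block. Of the 68 named genes that were called, 36 were called with the code block, 56 with limma-voom, 27 with the offset per chromosome and 31 to 56 with 1 library left out, and none changed sign over 1354 values. Uncalled genes that changed sign were mt-Co1 (-0.097 with the code block, -0.085 to 0.39 with 1 library left out), mt-Nd6 (-0.024 with the replicate block, -0.025 with the code block, -0.056 with limma-voom, -0.43 to 0.24 with 1 library left out) and, with the offset per chromosome, Spg7 (0.049) and Ndufb7 (0.024), both on chromosome 8. Where no reason is given, the cause was not tested. The share on mtDNA-encoded mRNAs differed by 0.74 with the replicate block (exact sign-flip p = 0.25) and by 0.19 to 1.11 with 1 library left out, never past the threshold. The differences of chromosomes 8, 14 and 6 kept their direction in all 13 alternatives each, but their p adjusted over 20 chromosomes was lost in 12 of the 13 for each (0.0529 to 0.106, for chromosome 6 to 0.136) and kept with upper-quartile scaling (0.0317). For chromosome 8 the unadjusted p stayed at 0.00794. A heteroplasmy level per library as a continuous term was not run, since no level was given. The self-test recovered 33.8% of 2-fold changes, so small changes in single genes are often below what 5 libraries per group can show.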

Other observations

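The BMP gene test, the count of genes on in 1 group and off in the other and the test around Eif4g3 concern patterns noticed in the data, though their tests were set before those values were seen. Genes of the bone morphogenetic protein (BMP) pathway were among the strong rises outside the fixed lists and were chosen after their values were seen. Id2 rose by 4.10, Id3 by 2.64 and Id1 by 2.67 on the log2 scale, which encode inhibitors of basic helix-loop-helix transcription factors and are direct BMP targets. The ligand gene Bmp2 rose by 5.62 (SE 1.27, adjusted p = 0.0345, edgeR) and the signal transducer gene Smad9 by 3.32 (SE 0.53, adjusted p = 0.012). To ask whether a wider BMP response may lie behind this, 9 further target genes not looked at before were tested together. They had a median of -0.61 and a camera p of 0.178, with Smad6 up by 1.83 (adjusted p = 0.022) and Nog at -3.45 (adjusted p = 0.0887). A p above the threshold over genes that go both ways cannot exclude a wider response, although that bound had been set beforehand, so the question stays open.

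Several genes were expressed in all libraries of 1 group and near absent from all of the other. With limits of under 0.5 CPM and over 1 CPM there were 13, of which 12 were on in the low group (Ildr2, Sgcd, Fam110c, Nr2f1, A830082K12Rik, Zic5, Epb41l4a, Blnk, Slco4a1, Dkk2, Eif4g3 and Trim71) and 1, Fam19a5, in the high group. No other of the 126 splits had more than 2. Such genes may mark different founder cells of the 2 groups, but the design confounds founder with heteroplasmy, so 13 genes cannot decide it: both cannot be told apart here. For Eif4g3, loss of a wider stretch of chromosome 4 is argued against by its 22 tested neighbours within 1 Mb, whose median log2 fold change was 0.12.

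Random grouping of the libraries is an unlikely source of the 630 changed genes: of 100 splits drawn from 126 distinct ones, 1 gave as many, the real one. The highest of the others gave 2. With only 126 distinct splits chance cannot be excluded, and the splits do not separate heteroplasmy from the founder cells of the groups. Nor can chance be excluded for the 9 shifted lists, since 73 of the 100 splits gave as many and the highest of the others gave 24. Whether the splits with many lists follow a structure among the libraries or the low preset correlation of camera was not tested, and the number of lists is no evidence of a shift with heteroplasmy.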
